A study of Mus musculus with 16 samples.

How the data were processed

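Transcript levels were measured in liver from 16 mice with Affymetrix MoGene 1.0 ST arrays, a whole-transcript microarray, with 1 array per animal. The design crosses 2 genotypes with 2 diets: mice carrying 1 null copy of Gli2, a transcription factor of the hedgehog signalling pathway, or wild-type mice, given a control or a high-fat diet for 12 weeks, with 4 animals in each of the 4 groups. The genotype field of the wild-type samples names Gli1, whereas the series text speaks of Gli2 only; these samples are treated here as wild type. The sex of the animals is not given in the sources used here, and their sex-linked transcripts read as female in all 16. The replicate numbers used here follow the order of the records and pair no animals. In the text Het stands for Gli2 heterozygous, and Het_control 2 for animal 2 of the heterozygous control group.

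The deposited values are log2 expression values, 1 per probe set, made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes; the versions are not given in the sources used here. RMA corrects the background, gives all arrays the same distribution of probe intensities and combines the probes of a probe set, so a level is relative to the other arrays and a global shift of all transcripts would be removed. The table holds 35556 probe sets. The platform annotation gives 1 gene symbol to 21789 of them, several symbols to 1621 and none to 12146. Probe sets with several symbols or none were left out of the tests by gene. Symbols were updated through the Entrez gene number with a mouse RefSeq table of assembly GRCm38.p6, which matched 19856 of the 19938 genes, and the other 82 kept the platform's symbol. Of the 19938 genes, 999 had more than 1 probe set and were represented by the one with the highest mean over the 16 arrays. No genome build is given for the array values, so no coordinates are printed and the RefSeq table was used only for names and for which genes lie near each other.

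Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust settings, with statmod 1.5.0 for the random block). All 16 arrays entered 1 fit with a mean for each group, so the groups share 1 estimate of the spread. The 6 contrasts tested were diet within each genotype, genotype within each diet, genotype averaged over both diets, and the diet by genotype interaction. P-values were adjusted over the 19938 genes of a contrast by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Each p-value by gene measures the spread between separate animals, as the series design describes them, and treats them as independent. The sample titles hold a number whose meaning is not stated. Of 11 such numbers, 5 were held by more than 1 array. Each of the 11 occurred in 1 genotype only, and 1 occurred in both diets. If animals with the same number share a cage or litter, they are not independent, and such an effect cannot be separated from genotype. In heterozygotes no number occurred in both diets, so there it cannot be separated from diet either. The number of arrays, 4 per group, limits the precision.

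Before the data were examined, 35 gene lists were fixed, covering pathways of lipid, sterol and glucose metabolism, stress and immune responses, hepatocyte zones, sex-biased liver genes, and markers of other cell types and tissues. At least 5 members of each were measured. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01 and adjusted over the 35 lists of a contrast. This value treats the genes of a list as nearly independent, so camera p is too small where they vary together between animals. A list described below as higher or lower is so at this setting. Camera compares a list with all other genes. It has no robust setting, so only trend moderation was tried for the lists, and it takes no random block, so the arrays were decorrelated first for that alternative. With the correlation estimated from the data no list was called in any of the 6 contrasts, and fry, which tests whether the genes of a list move on balance in 1 direction, called 1 list, in the diet contrast of heterozygotes. The genes to be named were set by a rule fixed at the same time. Gli2 and Gli1 are named in every contrast, with up to 10 called genes that rose most and 10 that fell most among named genes whose 2 groups of 4 arrays did not overlap. The overlap condition was left out for the interaction and for genotype over both diets. Where no gene was called, the 5 genes with the smallest p are named. For each list discussed, the 2 members with the smallest p are named. The lists discussed are the 6 with the smallest camera p in a contrast, and others are counted. Choosing 6 lists and 2 members was done after the data were examined, as was naming Lepr, Fabp5, Sult2a3 and Cd36 in the wild-type diet contrast, Pltp in heterozygotes, and the genes called in wild type without Het_control 2.

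The fit was tested on simulated data in which 200 of 19938 genes were changed in the diet contrast of heterozygotes. It recovered 80% of changes of 0.5 and 99% of changes of 1 on the log2 scale with all 16 arrays, and 85% and 97% without Het_control 2. In this simulation 7 of 186 calls with 16 arrays were false, and 11 of 193 without Het_control 2. The simulated values were drawn independently for each gene and array, with 1 spread per gene and no array apart from the rest. These rates therefore do not cover correlation between genes or an array such as Het_control 2.

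Alternatives fixed in advance were a repeated quantile normalization, median centring, a filter on dim genes, trend and robust moderation, only the arrays of a contrast, array weights, the number in the sample titles as a random block, the mean of a gene's probe sets, all probe sets, a minimum of 1.5-fold, camera with an estimated correlation, fry, and leaving out each array in turn. A sex-linked covariate was planned only if the difference between Xist and Y-linked genes spanned over 2 log2 units, and the span was 0.394. Leaving out Het_control 2, alone or with array weights, leaving out Het_control 2 and Het_control 4 together, and a test near Gli2 at an unadjusted p under 0.01 without Ctse were added after the data were examined. Figures were drawn with matplotlib 3.10.9.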

Results

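Liver transcript levels were measured in 16 mice in 4 groups of 4: wild type or Gli2 heterozygous, on a control or a high-fat diet for 12 weeks. The study set a reduced dose of a hedgehog pathway gene against a high-fat diet. Values are log2 RMA levels from 1 array per animal, and differences are given on the log2 scale with their standard error (SE). Het_control 2, animal 2 of the heterozygous control group, stood apart from the rest. Its correlation across genes with the other arrays was 0.948 to 0.970, against 0.986 to 0.996 among the other 15. The interquartile range of its values was 2.35, against 2.64 to 2.80 in the others. It was kept in all comparisons, and values without it are given for the main counts, lists and correlations.

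**Figure D1:**
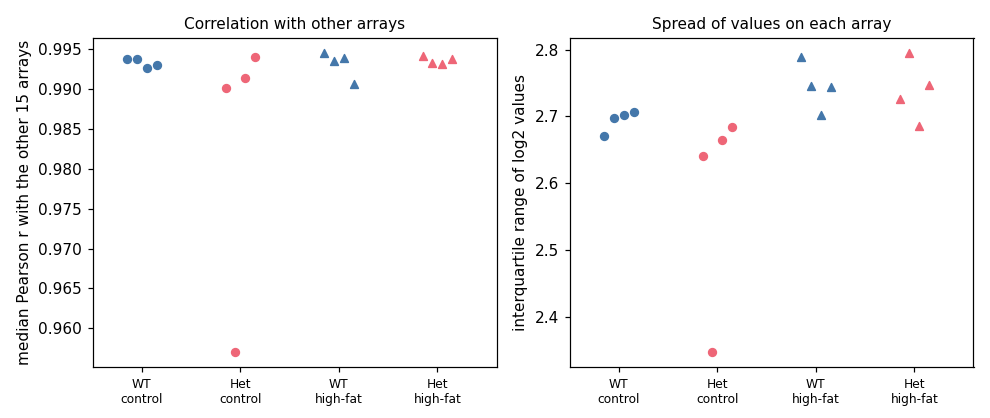
Each point is 1 array, by group (WT, wild type; Het, Gli2 heterozygous). The left panel shows the median Pearson correlation across genes with the other 15 arrays, the right panel the interquartile range of the log2 values; Het_control 2 lies lowest in both, with an interquartile range of 2.35.

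The Gli2 probe set was not called by genotype. Its level was 7.57 ± 0.02 (SD, n = 4) in wild type and 7.70 ± 0.30 in heterozygotes on control diet, and 7.51 ± 0.08 and 7.53 ± 0.07 on high-fat diet. The genotype difference over both diets was 0.08 (SE 0.07, limma adjusted p = 0.632), and the diet differences were -0.05 (SE 0.10, adjusted p = 0.967) in wild type and -0.17 (SE 0.10, adjusted p = 0.258) in heterozygotes. Het_control 2 read 8.14, the only array above 7.61. The deleted part of Gli2 is not given in the sources used here, and the probe set summarises probes along the transcript, so this level does not check the genotype labels. Gli1, a transcriptional target of the pathway, differed by 0.05 between genotypes over both diets (SE 0.04, adjusted p = 0.633). Of 24 measured members of the hedgehog pathway list, none was called by genotype, and the list was not shifted (camera adjusted p = 0.635 on control diet, 0.886 on high-fat diet and 0.596 over both). Adjusted over the list alone, 2 members were lower in heterozygotes on control diet, and 0 without Het_control 2, while 17 of the 24 were higher in value.

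In wild-type mice on the high-fat diet, lists of de novo lipogenesis, cell cycle, lymphocyte and ribosomal protein genes were lower. Lists of female-biased and acute phase genes were higher, while no single gene passed the threshold. The de novo lipogenesis list covers fatty acid and triglyceride synthesis and related genes. For de novo lipogenesis the median was -0.21 (camera adjusted p = 1.49e-05, or 0.619 with an estimated correlation), and 21 of 24 members were lower in value. Among them, Pnpla3, a protein of lipid droplets, read -1.05 (SE 0.22) and the acetyl-CoA carboxylase gene Acacb -0.53 (SE 0.19). For cell cycle genes the median was -0.13 (adjusted p = 6.81e-08; adjusted p = 0.510 with an estimated correlation), with the cyclin genes Ccna2 at -0.46 and Ccnb2 at -0.49. For lymphocyte genes it was -0.14 (adjusted p = 1.26e-05; adjusted p = 0.510 with an estimated correlation), with the B cell receptor component Cd79a at -0.47 and the interleukin 7 receptor Il7r at -0.31. All 17 ribosomal protein genes were lower in value, with a median of -0.12 (adjusted p = 3.54e-05; adjusted p = 0.510 with an estimated correlation), including Rplp0 at -0.17 and Rplp2 at -0.18. For female-biased liver genes the median was 0.24 (adjusted p = 2.83e-05; adjusted p = 0.510 with an estimated correlation), with Cux2 at 0.57 and Cyp3a16 at 0.85. For acute phase genes it was 0.05 (adjusted p = 0.000235; adjusted p = 0.510 with an estimated correlation), with the serum amyloid gene Saa1 at 0.86 and Steap4 at 0.37. No member of these 6 lists was called over all genes. Adjusted over the list alone, 1 lipogenesis gene, 7 cell cycle and 3 lymphocyte genes were lower, and 1 female-biased and 2 acute phase genes higher. Without Het_control 2 these counts were 2, 8, 7, 1 and 6. Single arrays moved some medians: without WT_HFD 4 that of female-biased genes was 0.12, without WT_control 4 that of ribosomal protein genes -0.08, and without WT_HFD 3, WT_HFD 4 and WT_control 1 that of acute phase genes 0.07, 0.09 and 0.03. In all, 10 lists were called, 9 of them also without Het_control 2, and 18 without WT_control 3.

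Among single genes in wild type, the smallest p belonged to the phospholipid transfer protein gene Pltp (-1.01, SE 0.16, limma adjusted p = 0.0975) and Amt, of the glycine cleavage system (0.49, SE 0.08, adjusted p = 0.0975). Ces1b (0.67), Fam214a (0.40) and Letm1 (0.39) followed, each with adjusted p = 0.205. Limma called 0 genes, and 1282 had an unadjusted p under 0.05, or 2704 without Het_control 2. Without Het_control 2, an array outside this contrast that enters the shared estimate of spread, 3 genes were called, with Amt higher and Pltp and Coro2a (-0.33) lower; these 3 were singled out after their values were seen. Without WT_control 3 there were 7 calls and without Het_control 3 there were 2, and array weights gave 219.

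In Gli2 heterozygotes the high-fat diet raised 300 genes and lowered 142. The largest rise among the named genes was in the sulfotransferase gene Sult2a3, 9.40-fold (3.23, SE 0.41, limma adjusted p = 0.00541), from 7.85 ± 0.79 (SD, n = 4) to 11.09 ± 0.36. Ly96, a co-receptor for lipopolysaccharide, rose by 2.04 (SE 0.45), Ly86 by 1.16 and the acute phase gene Saa2 by 1.11. The fatty acid translocase gene Cd36 rose by 1.44 (SE 0.26), the fatty acid binding protein gene Fabp7 by 1.28 and Eci3 by 1.06. The cytochrome P450 gene Cyp3a16 (1.60), Serpinb1a (1.29) and Igsf6 (1.03) rose as well. The largest fall was in the organic anion transporter gene Slco1a1, at -2.92 (SE 0.50). Another fatty acid binding protein gene, Fabp5, changed by -2.67 (SE 0.41), the leptin receptor gene Lepr by -2.20 (SE 0.32), Zbtb16 by -1.64 (SE 0.22) and the sulfotransferase gene Sult3a1 by -1.50. Hsd3b5 (-1.28), the phosphatidate phosphatase gene Lpin1 (-1.17), Rgs16 (-1.14), Serpina12 (-0.97) and the growth factor receptor gene Egfr (-0.97) fell as well. These 20 genes passed at adjusted p of 0.0372 or less. Without Het_control 2, Eci3 (0.83, adjusted p = 0.0621), Saa2 (0.95, adjusted p = 0.0705) and Serpina12 (-0.96, adjusted p = 0.0621) no longer passed. Leaving out 1 of the 8 heterozygous arrays in turn, Sult2a3, Slco1a1, Fabp5, Lepr, Zbtb16, Fabp7, Serpinb1a, Rgs16 and Egfr passed each time. The call of Hsd3b5 and that of Lpin1 were lost without Het_HFD 3 (adjusted p = 0.0561 and 0.0597), and that of Cd36 without Het_HFD 3 or Het_HFD 4, with adjusted p up to 0.0653. Cyp3a16 was lost without Het_HFD 1, 2 or 3 (adjusted p up to 0.0771). Igsf6 passed only without Het_control 2, 3 or 4, Ly96, Ly86 and Sult3a1 only without Het_control 2 or 4, Eci3 and Saa2 only without Het_control 4 or Het_HFD 1, and Serpina12 only without Het_control 4. Their highest adjusted p were 0.102, 0.103, 0.113, 0.0944, 0.098, 0.107 and 0.113. All of these differences kept their sign. With only the 8 heterozygous arrays fitted, Sult2a3, Slco1a1, Fabp5, Zbtb16, Egfr and Serpina12 passed. The others did not, including Lepr (adjusted p = 0.109), Fabp7 (0.109), Serpinb1a (0.107) and Rgs16 (0.114).

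**Figure D2:**
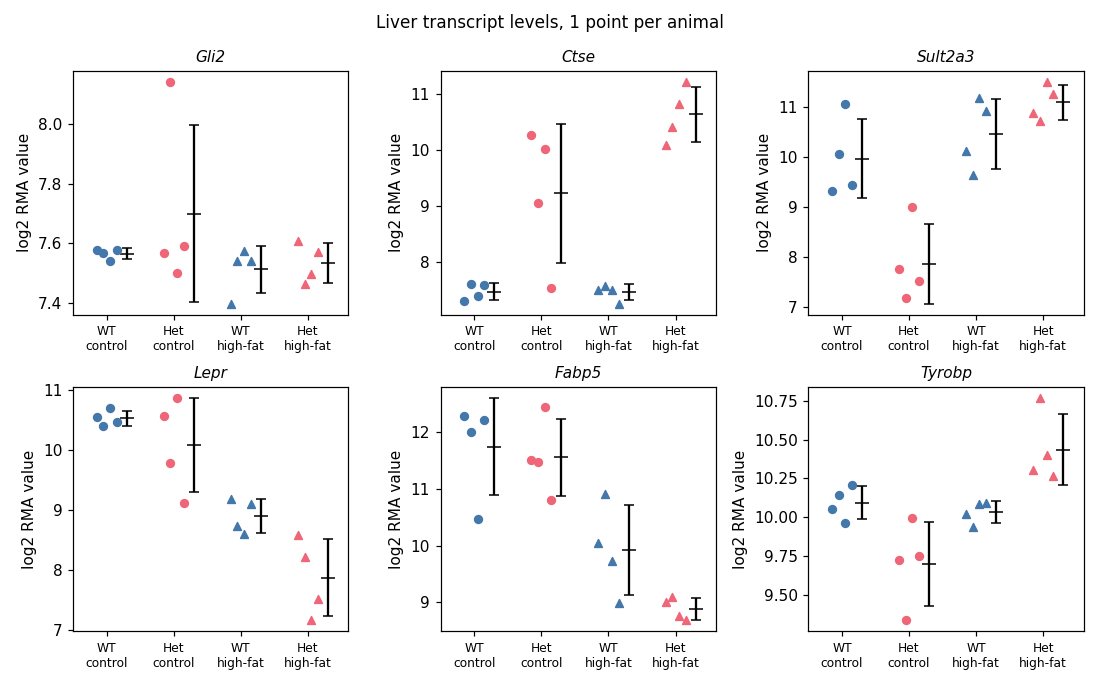
Log2 RMA values of 6 genes, 1 point per animal, by group, with the group mean and SD (bars) beside the 4 points. Ctse is at 7.25 to 7.60 in all 8 wild-type animals and at 7.53 in 1 of the 8 heterozygotes; Gli2 differs from the rest in Het_control 2 alone.

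Macrophage and Kupffer cell genes were higher as a list in heterozygotes on the high-fat diet, and 10 of the 33 measured rose while 1, the tetraspanin gene Cd9, fell; without Het_control 2, 4 rose and 1 fell. The median was 0.20, or 0.24 without Het_control 2, 0.13 without Het_control 4 and 0.13 without Het_HFD 2 (camera adjusted p = 8.49e-07; adjusted p = 0.467 with an estimated correlation). The signalling adaptor gene Tyrobp rose by 0.74 (SE 0.12) and the complement gene C1qb by 0.63 (SE 0.12). Of 17 interferon response genes 3 rose, or 2 without Het_control 2, Rsad2 by 0.76 (SE 0.15) and the chemokine gene Cxcl10 by 0.92 (SE 0.18) among them. Their median was 0.38, or 0.27 without Het_control 2 (adjusted p = 1.65e-07; adjusted p = 0.467 with an estimated correlation). Of 26 genes of xenobiotic metabolism 3 rose, or 1 without Het_control 2, with a median of 0.29, or 0.18 without Het_control 2 (adjusted p = 3.43e-05; adjusted p = 0.467 with an estimated correlation). Of 19 female-biased genes 4 rose, or 3 without Het_control 2, Cd36 and Cyp3a16 among them, and 2 fell, Sult3a1 and Spink1. Their median was 0.37, or 0.29 without Het_control 2 (adjusted p = 0.000521; adjusted p = 0.498 with an estimated correlation). Of 32 genes of fatty acid oxidation 1 rose, the aldehyde dehydrogenase gene Aldh3a2 (0.39, SE 0.10), and Acot2 read 0.74 (adjusted p = 0.0567). Their median was 0.17, or 0.12 without Het_control 2 (adjusted p = 1.93e-05; adjusted p = 0.574 with an estimated correlation). Of 18 oxidative stress genes 1 rose, the quinone reductase gene Nqo1 (0.64, SE 0.14), and Ephx1 read 0.58 (adjusted p = 0.0512). Their median was 0.16, or 0.18 without Het_control 2 (adjusted p = 2.36e-05; adjusted p = 0.467 with an estimated correlation). Aldh3a2 (0.28, adjusted p = 0.0719) and Nqo1 (0.59, adjusted p = 0.0684) no longer passed without Het_control 2, so that 0 genes of their lists did. Leaving out 1 heterozygous array in turn, Tyrobp passed each time. C1qb was lost without Het_HFD 1, 2 or 3, Rsad2 without Het_HFD 2, 3 or 4, and Cxcl10 without Het_control 3, Het_HFD 2 or Het_HFD 3 (adjusted p up to 0.0822, 0.076 and 0.0824). Nqo1 passed only without Het_control 3, Het_control 4 or Het_HFD 1, and Aldh3a2 only without Het_control 1 or 4 (adjusted p up to 0.118 and 0.127). With only the 8 heterozygous arrays fitted none of these 6 passed, Tyrobp at adjusted p = 0.129.

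Adjusted over the list alone, 13 macrophage genes rose and 1 fell, 11 interferon, 12 xenobiotic, 6 fatty acid oxidation and 8 oxidative stress genes rose, and of female-biased genes 8 rose and 2 fell. Without Het_control 2 these counts were 15 and 1 for macrophages, 8, 4, 0 and 6 for the next lists, and 7 and 2 for female-biased genes. In all, 16 lists were called, 14 of them also without Het_control 2. Class II antigen presentation genes were higher too, with a median of 0.33, or 0.24 without Het_control 2 and 0.11 without Het_HFD 2 (camera adjusted p = 0.00053; adjusted p = 0.574 with an estimated correlation), and 2 of 10 rose, or 0 without Het_control 2. Endothelial cell genes had a median of 0.18, or 0.11 without Het_control 2 and 0.28 without Het_control 3 (camera adjusted p = 0.00053; adjusted p = 0.588 with an estimated correlation), and 19 of 24 were higher in value. This list was not called after a repeated quantile normalization (adjusted p = 0.158). Markers of other tissues were lower, with a median of -0.19 for gallbladder and gut genes and -0.13 for pancreas genes, or -0.10 and -0.06 without Het_control 2 (camera adjusted p = 0.00263 and 0.00416; adjusted p = 0.588 with an estimated correlation for both). Neither list was called after a repeated quantile normalization (camera adjusted p = 0.0581 and 0.173). The dimmer part of all genes had a median difference of -0.13 and the brighter part 0.07, against -0.05 and 0.02 without Het_control 2.

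The number of genes called in heterozygotes varied with the arrays used. Without Het_control 2, 174 genes were called (116 higher, 58 lower), 161 of them among the 442, and the fit on the 8 heterozygous arrays alone called 7 (2 higher, 5 lower). Leaving out 1 array gave 3446 calls without Het_control 4 (1868 higher, 1578 lower), 191 without Het_control 1, 139 without Het_control 3, and 127, 50, 45 and 52 without Het_HFD 1, 2, 3 and 4. Arrays outside the contrast moved it too, with 121, 144, 284 and 197 calls without WT_control 1, 2, 3 and 4, and 193 and 190 without WT_HFD 1 and 3. After a repeated quantile normalization 204 of the genes changed by diet in Gli2 heterozygotes were higher and 167 lower. All probe sets gave 54 higher and 41 lower. With the title number as a random block more genes fell than rose, 2896 higher and 4042 lower.

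Diet responses of the genotypes were correlated across genes, which are not independent replicates, with a Pearson's r of 0.469 (Spearman 0.433) over 19938 genes, or 0.416 (Spearman 0.339) without Het_control 2. Lepr, Fabp5, Sult2a3 and Cd36, singled out after their values were seen, differed by -1.62, -1.82, 0.49 and 0.19 in wild type, with limma adjusted p of 0.205, 0.263, 0.922 and 0.949. Of the 442 genes called in heterozygotes, 333 had the same sign in wild type. Pltp, singled out in the same way, read -0.60 in heterozygotes (adjusted p = 0.0525). No gene passed the test of a difference between these responses, the interaction described last.

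On control diet, lists of endothelial cell, fatty acid oxidation, interferon response, cell cycle, xenobiotic metabolism and macrophage genes were lower in heterozygotes than in wild type, and no single gene passed. For endothelial cell genes the median was -0.29, or -0.18 without Het_control 2 (camera adjusted p = 1.7e-09; adjusted p = 0.455 with an estimated correlation), with the Fc receptor gene Fcgr2b at -0.43 (SE 0.12) and the cadherin gene Cdh5 at -0.34 (SE 0.11). For fatty acid oxidation it was -0.17, or -0.11 without that array (adjusted p = 7.06e-08; adjusted p = 0.455 with an estimated correlation), with the pyruvate dehydrogenase kinase gene Pdk4 at -0.82 and Acot2 at -0.78. For interferon response it was -0.24, or -0.19 without it (adjusted p = 7.06e-08; adjusted p = 0.455 with an estimated correlation), with Rsad2 at -0.82 and Ifit3 at -0.74. For cell cycle it was -0.19, or -0.18 without it (adjusted p = 2.45e-07; adjusted p = 0.455 with an estimated correlation), with the proliferation marker Mki67 at -0.66 and Ccna2 at -0.53. For xenobiotic metabolism it was -0.22, or -0.11 without it (adjusted p = 8.36e-07; adjusted p = 0.455 with an estimated correlation), with Cyp2c55 at -0.92 and Cyp3a16 at -1.17. For macrophages it was -0.04, or -0.12 without it (adjusted p = 0.000443; adjusted p = 0.501 with an estimated correlation), with Cd68 at -0.38 and Tyrobp at -0.39. Adjusted over the list alone, 10 endothelial, 5 fatty acid oxidation, 6 interferon, 10 cell cycle, 3 xenobiotic and 5 macrophage genes were lower. Without Het_control 2 these counts were 0, 0, 4, 7, 2 and 0. The macrophage median was 0.01 without Het_control 4, -0.08 without WT_control 3 and -0.03 without WT_control 4. Gallbladder and gut genes (median 0.14) and pancreas genes (0.10) were higher, with medians of 0.04 and 0.03 without Het_control 2 (adjusted p = 0.00684 and 0.00865; adjusted p = 0.501 and 0.618 with an estimated correlation). The pancreas call was lost without Het_control 2 (adjusted p = 0.132), and neither list was called after a repeated quantile normalization (adjusted p = 0.0944 and 0.2). The dimmer part of all genes had a median difference of 0.10 and the brighter part -0.04, against 0.02 and -0.0008 without Het_control 2. In all, 16 lists were called, 8 of them also without Het_control 2.

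Among single genes on control diet, Sult2a3 read -2.11 (SE 0.41), Rsad2 -0.82 (SE 0.15), H2-K2 -0.43 (SE 0.08), Fam214a 0.41 (SE 0.08) and Ube2g2 0.41 (SE 0.08), the 5 with the smallest p, all with limma adjusted p = 0.279. Limma called 0 genes, and 3135 had an unadjusted p under 0.05, or 1602 without Het_control 2. Without Het_control 4, 18 genes were called.

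On high-fat diet 1 gene differed by genotype, the aspartic protease gene Ctse (cathepsin E, probe set 10349648). It was 9.12-fold higher in heterozygotes (3.19, SE 0.41, 95% interval 2.33 to 4.04, limma adjusted p = 0.00958), with a mean of 10.64 ± 0.49 (SD, n = 4) against 7.45 ± 0.14 in wild type. Over both diets the difference was 2.48 (SE 0.29, adjusted p = 0.00267), and Ctse was the only gene called there too. On control diet the difference did not pass (1.76, SE 0.41, adjusted p = 0.279, or 1.82 and adjusted p = 0.372 without Het_control 2). There 3 of 4 heterozygotes read 9.06 to 10.27 and Het_control 4 read 7.53, within the wild-type range. The high-fat call was lost without any 1 of WT_HFD 1, WT_HFD 3, WT_HFD 4, Het_HFD 3 or Het_HFD 4, where the difference stayed at 2.99 to 3.20 and the adjusted p was 0.0546, 0.0551, 0.075, 0.0696 and 0.0752. Without Het_HFD 1, 2 genes were called on high-fat diet and 2 over both diets, and with all probe sets tested no probe set was called on high-fat diet.

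To look at the surroundings of the altered gene, genes on chromosome 1 near Gli2 were counted. Ctse lies within 20 Mb of Gli2, so 1 of 183 genes there was called over both diets against 0 of 19755 others (Fisher's exact test, two-sided, p = 0.00918). With 1 call in all, this p is the share of tested genes that lie in the window and does not show that calls gathered there. With the title number as a random block, 2 of 183 genes there were called against 5 of 19755 others (Fisher's exact p = 0.00171, odds ratio 43.6). The added gene, Serpinb3d, was singled out after its values were seen and read 0.24 with the block (adjusted p = 0.0348) and 0.23 without it (adjusted p = 0.409). Ctse is the other of the 2 genes. The fit with the block, at a consensus correlation of -0.372, called more genes in every contrast, so its Fisher p does not show that calls gathered near Gli2 either. Within 10 Mb, 0 of 48 genes were called (Fisher's exact p = 1).

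Beside Ctse, lists of macrophage, class II antigen presentation, lymphocyte and cell cycle genes were higher in heterozygotes on high-fat diet, and lists of bile acid and cholesterol transport and of sterol synthesis lower. For macrophages the median was 0.22 (camera adjusted p = 7.47e-13; adjusted p = 0.468 with an estimated correlation), with the cytokine gene Il1b at 0.62 (SE 0.14) and C1qb at 0.41 (SE 0.12). For class II it was 0.24 (adjusted p = 1.22e-07; adjusted p = 0.468 with an estimated correlation), with Ifi30 at 0.30 and H2-DMa at 0.44. For lymphocytes it was 0.12 (adjusted p = 8.01e-07; adjusted p = 0.468 with an estimated correlation), with Il7r at 0.37 and Cd79a at 0.43. For cell cycle it was 0.08 (adjusted p = 0.000452; adjusted p = 0.817 with an estimated correlation), with the replication genes Mcm5 at 0.29 and Mcm2 at 0.26. For bile acid and cholesterol transport it was -0.09 (adjusted p = 3.68e-05; adjusted p = 0.468 with an estimated correlation), with the sterol transporter genes Abcg8 at -0.29 and Abcg5 at -0.20. For sterol synthesis it was -0.11 (adjusted p = 0.000643; adjusted p = 0.847 with an estimated correlation), with Stard4 at -0.27 and Nsdhl at -0.27. No member of these lists passed over all genes. With p adjusted over the list alone, 6 macrophage, 2 class II, 2 lymphocyte and 2 cell cycle genes were higher, and 1 bile acid transport gene was lower; without Het_control 2 these counts were 9, 3, 5, 2 and 2, and 1 sterol synthesis gene was lower. In Het_HFD 2, class II genes had a median of 0.72 above the mean of all arrays, against -0.03 to 0.03 in the other 3 animals of its group. Without it the medians were 0.07 for class II, 0.14 for macrophages and -0.06 for sterol synthesis, and the lymphocyte list was no longer called (0.09, camera adjusted p = 0.0579). Without Het_HFD 4 the cell cycle median was 0.05. In all, 10 lists were called, 8 of them also without Het_control 2.

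Averaged over both diets, lists of fatty acid oxidation, xenobiotic metabolism, endothelial cell, sterol synthesis, interferon response and female-biased genes were lower in heterozygotes. Their medians were -0.10, -0.11, -0.11, -0.13, -0.11 and -0.09, or -0.08, -0.07, -0.07, -0.06, -0.08 and -0.03 without Het_control 2. Camera gave adjusted p of 1.24e-08, 4.03e-08, 7.33e-07, 5.59e-06, 1.27e-05 and 1.44e-05, and each had adjusted p = 0.490 with an estimated correlation. The fatty acid hydroxylase genes Cyp4a10 and Cyp4a31 read -0.29 and -0.40, Cyp3a16 -0.79 and the carboxylesterase gene Ces2a -0.25. Of endothelial genes, Lyve1 read -0.31 and Oit3 -0.19, and of sterol genes, Tm7sf2 read -0.25 and Stard4 -0.19. Rsad2 read -0.39, Ifit3 -0.38 and Sult3a1 -0.91, and all of these genes had limma adjusted p = 0.573. With p adjusted over the list alone, 3 xenobiotic, 2 sterol synthesis, 1 interferon and 3 female-biased genes were lower, and without Het_control 2 these counts were 0, 0, 1 and 2. The endothelial median was -0.07 without WT_HFD 4, and that of female-biased genes was -0.16, -0.14, -0.18, -0.06 and -0.17 without Het_control 3, Het_control 4, WT_HFD 2, WT_control 3 and WT_control 4. An average over diets does not show a difference on each diet. Fatty acid oxidation, endothelial and interferon genes had medians of -0.17, -0.29 and -0.24 on control diet. Their interaction medians were 0.19, 0.32 and 0.29, in the opposite direction. That of fatty acid oxidation was 0.09 without Het_control 2 and no longer called (camera adjusted p = 0.0554). Rsad2 read -0.82 on control diet, with an interaction of 0.85. For these lists the average thus reflects mainly the control diet. The dimmer part of all genes had a median difference of 0.06 and the brighter part -0.02, against 0.02 and 0.0008 without Het_control 2. In all, 15 lists were called, 11 of them also without Het_control 2. Genotype differences on the control and high-fat diets had a Pearson's r of 0.038 across genes (Spearman 0.048), or -0.043 (Spearman -0.053) without Het_control 2.

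In the test of the diet by genotype interaction, lists of macrophage, cell cycle, endothelial cell, class II antigen presentation, interferon response and lymphocyte genes had a more positive diet difference in heterozygotes than in wild type, and no single gene passed. For macrophages the median was 0.23, or 0.31 without Het_control 2 and 0.14 without Het_control 4 (camera adjusted p = 2.62e-11; adjusted p = 0.417 with an estimated correlation), with Cd68 at 0.71 (SE 0.15) and Tyrobp at 0.79 (SE 0.17). For cell cycle it was 0.26, or 0.27 without that array (adjusted p = 2.24e-10; adjusted p = 0.417 with an estimated correlation), with the mitotic kinase gene Plk1 at 0.63 and Ccnb2 at 0.76. For endothelial cells it was 0.32, or 0.20 without it (adjusted p = 5.1e-08; adjusted p = 0.540 with an estimated correlation), with Cdh5 at 0.48 and Fcgr2b at 0.50. For class II it was 0.44, or 0.37 without it and 0.23 without Het_HFD 2 (adjusted p = 1.07e-07; adjusted p = 0.417 with an estimated correlation), with Ifi30 at 0.52 and H2-DMa at 0.81. For interferon response it was 0.29, or 0.18 without it (adjusted p = 9.4e-07; adjusted p = 0.459 with an estimated correlation), with Rsad2 at 0.85 and Cxcl10 at 0.84. For lymphocytes it was 0.16, or 0.18 without it and 0.08 without Het_HFD 2 (adjusted p = 0.000162; adjusted p = 0.540 with an estimated correlation), with Cd79a at 0.72 and Il7r at 0.50. Adjusted over the list alone, 12 macrophage, 9 cell cycle, 3 class II, 2 interferon and 3 lymphocyte genes were higher, and without Het_control 2 these counts were 14, 11, 2, 1 and 8. For the macrophage median, 5 of 100 splits of the arrays within each diet gave one as large in size, the real one included. The dimmer part of all genes had a median interaction of -0.09 and the brighter part 0.04, against -0.01 and 0.003 without Het_control 2. In all, 12 lists were called, 7 of them also without Het_control 2.

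**Figure D3:**
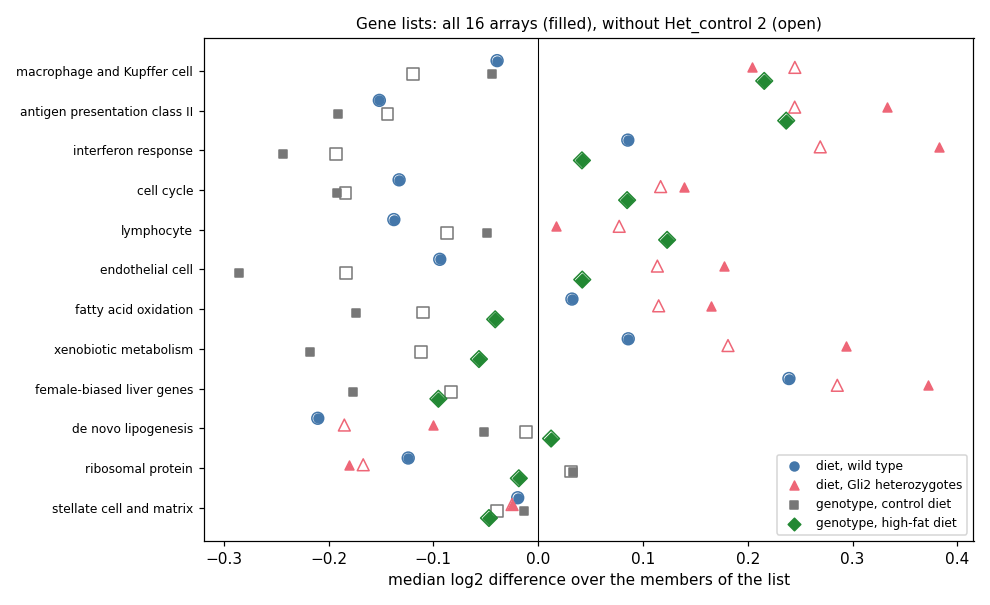
Median log2 difference over the members of 12 gene lists, for diet in each genotype and genotype on each diet. Filled marks use all 16 arrays and open marks leave out Het_control 2; the macrophage list has a median of 0.20 for diet in heterozygotes and -0.04 for genotype on control diet.

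Among single genes in the interaction, the smallest p belonged to Emp3 (0.61, SE 0.11), Ms4a8a (0.55, SE 0.10), the kinase gene Sik1 (1.18, SE 0.23), Cd72 (0.66, SE 0.13) and Fam214a (-0.53, SE 0.11), each with limma adjusted p = 0.240. Limma called 0 genes, and 1621 had an unadjusted p under 0.05.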

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

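The tests of signal range, of gut or blood RNA, of the array that stands apart and of the share of hepatocytes were chosen after the results they bear on were seen, and so was the test of strain variants without Ctse. An array was looked at again where its gap to the nearest of the others in its group of 4, divided by the group's range, was above Dixon's 95% critical value. This held in 32 of 380 groups, where chance alone gives about 1 in 20, or 19. Het_control 2 accounted for 10 of them.

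Het_control 2 was far from its group in median level (8.14), interquartile range (2.35) and median correlation with other arrays (0.957), in Gli2 (8.14), Fabp7 (8.21) and Ly86 (8.25), and in the medians of acute phase (-0.292), bile acid and cholesterol transport (-0.307), interferon response (-0.576) and lymphocyte genes (0.189), given as deviations from the mean of all arrays. The tables argue against RNA of another tissue: over 5 lists of adipocyte, pancreas, gut, muscle and blood genes, the highest median was 0.095 above genes of the same level, where over 1 was required. A loss of signal range on that array stays open and may account for part of the distance. Its deviation fell with gene level at a slope of -0.130, against -0.021 to 0.048 in the other 15 arrays. A difference in the state of this animal was not tested.

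Ctse was called higher in heterozygotes on high-fat diet and over both diets. On control diet the difference of 1.76 did not pass (adjusted p = 0.279), with Het_control 4 at the wild-type level. The tables argue against RNA of gut or blood, since the larger of the 2 list medians was 0.0786 over both diets, where over 0.5 was required. They also argue against the array that stands apart, since the adjusted p without it was 0.00556 (limma). Strain variants carried along in the chromosome 1 segment around Gli2 may account for it and cannot be told apart from an effect of the genotype. Of the genes within 20 Mb, Ctse left out, 1.65% had an unadjusted p under 0.01 against 1.22% of other genes (Fisher's exact p = 0.491, odds ratio 1.36, interval 0.275 to 4.08).

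The macrophage list rose with diet more in heterozygotes than in wild type, with a median difference of 0.226. The array that stands apart is argued against, since the median without it was 0.314. A lower share of hepatocytes in the heterozygotes on high-fat diet cannot be told apart from a change in macrophages. The stellate cell list (-0.0323) and the cholangiocyte list (-0.0562) lay below the macrophage list, with permutation p of 7e-05 and 8e-05 across genes, which are not independent. The larger gap was 0.282, within the SD of 0.332 over the macrophage genes. That SD is a spread of single genes and not the error of a median, so it cannot decide. With all arrays the endothelial list (0.320) lay as high. Without Het_control 2 the stellate, cholangiocyte and endothelial medians were -0.0402, -0.0670 and 0.198. The macrophage median was then 0.314, so the endothelial list no longer lay as high. Without Het_control 4 the macrophage median was 0.137, so that animal may account for part of the difference. Chance could not be excluded either, since 5 of 100 splits of the arrays within each diet gave a median as large in size, the highest other being 0.314.

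Other lists differed in diet response between genotypes by camera on the interaction: cell cycle (0.264), endothelial cell (0.320), class II antigen presentation (0.442), interferon response (0.291), lymphocyte (0.156), fatty acid oxidation (0.185), oxidative stress (0.121), xenobiotic metabolism (0.160), circadian clock (0.107), gallbladder and gut (-0.0899) and lipid droplet (0.0121) genes. None was called with an estimated correlation, with adjusted p = 0.417 to 0.878 with an estimated correlation. Without Het_control 2, fatty acid oxidation (adjusted p = 0.0554), xenobiotic metabolism (0.435), circadian clock (0.340), gallbladder and gut (0.340) and lipid droplet genes (0.265) were no longer called. Their medians were then 0.0902, 0.0342, 0.0427, -0.0169 and 0.0179, and that of oxidative stress 0.0652. Fatty acid oxidation was 0.122 without Het_control 3. Xenobiotic metabolism was 0.246 without WT_control 4 and was lost without WT_control 3 (0.0960). The clock list was lost without WT_control 1 (0.0622), WT_control 3 (0.0539), WT_HFD 3 (0.0760), Het_HFD 1 (0.0998) and Het_HFD 2 (0.102) as well, and was 0.18, 0.18 and 0.17 without WT_control 4, Het_control 4 and WT_HFD 2. The gut list was also lost without WT_control 2 and 3 (-0.08 and -0.09), Het_control 4 (-0.13), WT_HFD 1 and 3 (-0.09 and -0.08), and Het_HFD 2 and 4 (-0.08 and -0.10). The lipid droplet list was lost without 10 of the 16 arrays, all but WT_control 2, Het_control 1 and 3, WT_HFD 2, and Het_HFD 1 and 2. Its median was -0.00356 to 0.0826 over all 16 of these fits, kept and lost, and -0.0238 after a repeated quantile normalization.

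Single arrays far from their group in 1 gene were, in WT_control 3, Acacb (11.22), Fabp5 (10.47), Rsad2 (9.26) and Steap4 (11.12), and in WT_control 4, Cdh5 (10.61), Emp3 (9.64) and Fabp7 (10.11). WT_control 2 was apart in Lyve1 (10.09) and WT_HFD 4 in Fabp7 (10.42). Het_control 3 was apart in Fam214a (11.32), Il7r (6.30), Pltp (12.08) and Rgs16 (13.28). Het_HFD 1 was apart in Ces1b (12.19) and Cux2 (10.27), Het_HFD 2 in H2-DMa (9.88) and Nsdhl (11.28), and Het_HFD 4 in Cyp3a16 (10.77). In list medians, WT_control 1 was apart in acute phase (-0.138), WT_HFD 1 in lymphocytes (-0.0606), and class II was apart in WT_HFD 2 (-0.211) and Het_HFD 2 (0.717).

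Regrouping the same arrays tested the counts of genes. For diet in heterozygotes, 1 of 35 splits gave as many as 442 genes, the real one, and the highest other gave 2. Without Het_control 2, the real split also stood apart with 174 genes, as 1 of 35 splits and with a highest other of 3. This does not exclude chance, since 1 of 35 is the smallest share possible. Splits that mix the diets also move a diet effect into the spread, which holds their counts low. For genotype over both diets 4 of 100 splits called at least the 1 gene, but the highest other called 2, so the count alone does not set the real split apart. Chance could not be excluded for genotype on high-fat diet, where 3 of 35 splits called at least 1 gene and the highest other 2. With 0 genes called, every split gives as many, so the splits say nothing on chance for diet in wild type (35 of 35 splits, highest other 0), genotype on control diet (35 of 35, highest other 8) or the interaction (100 of 100, highest other 1).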

How the results depend on the processing

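Leaving out Het_control 2, with and without array weights, leaving out Het_control 2 and 4 together, and the test near Gli2 at an unadjusted p without Ctse were chosen after the data were examined. No paired analysis was possible because the replicate numbers follow the order of the records and pair no animals. Of 28 called results of named genes, 429 of 536 recomputed values passed in the same direction, 107 no longer passed and 0 changed sign. Of these calls, 20 were lost with only the arrays of the contrast, where fewer arrays estimate the spread, 8, 5 and 8 without Het_control 1, 2 and 3, and 8, 13, 17 and 12 without Het_HFD 1, 2, 3 and 4. Aldh3a2 did not pass after a repeated quantile normalization (adjusted p = 0.0593) or median centring (adjusted p = 0.0502). Of 93 results not called, 1878 of 1969 values stayed so in the same direction, 68 passed and 23 changed sign. For the other changes given here the cause was not tested.

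Array weights gave 219 genes for diet in wild type, 1067 for diet in heterozygotes, 3 for genotype on high-fat diet and 1 for the interaction. The title number as a random block, with a consensus correlation of -0.372 and a meaning that is not stated, gave 40 and 6938 for diet in wild type and heterozygotes, 2, 3 and 7 for genotype on control diet, high-fat diet and both, and 2 for the interaction. Only the arrays of the contrast gave 6 and 7 for diet and 2 for genotype on high-fat diet. All probe sets gave 95 for diet in heterozygotes and 0 for genotype on high-fat diet, and a minimum of 1.5-fold gave 123 for diet in heterozygotes. Without Het_control 2 the diet counts were 3 and 174, and with array weights as well 149 for diet in wild type, 3 for genotype on high-fat diet and 1 for the interaction. Without Het_control 2 and 4 there were 16 and 805 for diet, 4 for genotype on control diet and 3 for the interaction.

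Lists called fell to 0 in all 6 contrasts with an estimated correlation, and fry called 1 for diet in heterozygotes and 0 in each of the other 5. A repeated quantile normalization gave 9 for genotype over both diets and 7 for the interaction, and the brighter part of the genes gave 7, 8 and 6 for genotype on control diet, genotype over both diets and the interaction. Near Gli2, Fisher's exact test in the window of 10 Mb gave p = 1, the wide window of 40 Mb p = 0.0208, and the test without Ctse p = 0.491. With the title block Fisher's exact test gave p = 0.00171, with 2 of 183 genes called near Gli2, Ctse among them, against 5 of 19755 others.

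Leaving out each array in turn gave 0 to 7 genes for diet in wild type, 45 to 3446 for diet in heterozygotes, 0 to 18, 0 to 2 and 1 to 2 for genotype on control diet, high-fat diet and both, and 0 for the interaction. Lists ranged over 9 to 18, 15 to 18, 12 to 19, 7 to 12, 11 to 17 and 9 to 15 in the same order. Pearson's r ranged from 0.368 to 0.515 between diet responses (jackknife SE 0.132) and from -0.128 to 0.145 between genotype responses (jackknife SE 0.253).

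The changes of sign were in differences near 0. Gli2 by genotype on control diet was -0.01259 without Het_control 2, -0.01257 with array weights, -0.02368 with both and -0.0316 without Het_control 2 and 4, and Gli1 was -0.02608, -0.02746, -0.03259 and -0.04046. The Gli2 interaction was 0.0348, 0.07814, 0.09023 and 0.05381 in the same order. With each array left out in turn the highest value was 0.2012 for Gli2 and 0.07495 for Gli1 on control diet, and the lowest Gli2 interaction was -0.179. Gli2 by diet in heterozygotes was 0.004465 without Het_control 2 with array weights and 0.001288 without Het_control 2 and 4, where Gli2 over both diets was -0.004696. Gli2 by genotype on high-fat diet was -0.001923 with the title block, -0.002619 without Het_HFD 1 and -0.01626 without WT_HFD 1, the lowest with 1 array left out, where the highest was 0.04641. With 1 array left out, the Gli1 interaction ranged from -0.01602 (without Het_control 3) to 0.08501, and Cd36 by diet in wild type from -0.001717 (without WT_HFD 4) to 0.3607.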

Other observations

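The diet score below was chosen after the level of Ctse in Het_control 4 was seen. Immediate early genes were higher in heterozygotes over both diets (median 0.13, or 0.10 without Het_control 2, camera adjusted p = 0.0102; adjusted p = 0.490 with an estimated correlation), and the call was lost without Het_control 1 (median 0.09, adjusted p = 0.096). Circadian clock genes were higher with diet in heterozygotes (median 0.12, adjusted p = 0.00168; adjusted p = 0.467 with an estimated correlation), a call that a repeated quantile normalization ended (adjusted p = 0.158). Of the 35 lists, 10 were called in no contrast, with a smallest adjusted p of 0.122: hedgehog pathway, glucose and insulin response, endoplasmic reticulum stress, periportal hepatocyte, male-biased liver genes, sex-chromosome transcripts, cholangiocyte and progenitor, erythroid and blood, adipocyte and skeletal muscle genes. Xist read 12.60 to 12.94 in the 16 animals and the mean of 3 Y-linked genes 5.26 to 5.60, with no array out of place. On every array Xist lay above the upper quartile and the Y-linked mean below the lower quartile, the pattern of female animals.

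Het_control 4 was at the wild-type level of Ctse (7.53). The other heterozygotes read higher on both diets, so this level does not bear on its diet label. A wrong genotype label or a recombination between Gli2 and Ctse was not tested and stays open.

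More genes were called by diet in heterozygotes without Het_control 4 (3446 against 442), and a wrong diet label may be a candidate explanation for that. A score built from the 100 genes with the smallest diet p in the 8 wild-type arrays alone put the wild-type control mean at 0 and the wild-type high-fat mean at 1. Het_control 4 scored 0.698, between the highest other control array (0.241) and the lowest high-fat array (0.903), so a wrong diet label cannot be told apart from a control animal with a diet-like profile. Het_control 4 had its highest correlation with WT_HFD 1 (Pearson's r of 0.996). WT_HFD 1 was also the closest array for the control-diet array WT_control 3 and for several high-fat arrays, so this says little about diet. Its Lepr level of 9.12 lay within the wild-type high-fat range of 8.60 to 9.18. Its Sult2a3 level of 7.51, however, lay among the other heterozygous controls (7.17 to 8.99). A wrong label of both genotype and diet was not tested and stays open. The animal was kept in its labelled group.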
